A study of Homo sapiens with 10 samples.

How the data were processed

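HCT116 cells were profiled by ribosome profiling (3 libraries), mRNA-seq (3), YTHDF1 RIP with its input (1 each) and m6A-seq (2), 10 samples in all. Groups came from the sample labels. Per the labels, cells were treated with cycloheximide at 100 ug/ml for 3 min, and per the file headers the control hairpin targets GFP. The sample titles name the knockdown hairpin as shY1-1 or shY1-2, here knockdown 1 and 2, while the genotype field gives shY1 for each of these samples. The labels therefore do not settle whether these are different hairpins or repeats of 1 hairpin.

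Per the submitters' processing notes STAR and the GRCh38 build were used, and versions are not given in the sources used here. The expression table holds a deposited signal per gene, a relative abundance whose unit the file headers do not name. No whole-read steps were found in its low values, so depth is unknown and no count model was used. Every control value in both assays is at least 0.5, while knockdown values reach 0 (178 and 37 genes in footprints, 5 and 7 in mRNA), so the table was filtered on the control. This selects against genes that were low in the control and present in the knockdown. The highest 10 genes held 36.0% of the control footprint values, 25.5% in knockdown 1 and 37.2% in knockdown 2. RPL3 alone made up 18.9% of the control footprint total. The RIP list holds FPKM values deposited by the authors with their ratio, and shows only genes with ratios of at least 1.5. The m6A lists hold, per the file headers, signals in immunoprecipitate and input and a deposited ratio of peak over input of at least 3, called per replicate. These peak ratios are the authors' own and were used only within each list. Peak positions run along an unnamed transcript. The peak caller is not given in the sources used here.

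Values were put on the log2(value + 1) scale, which understates changes of low genes. Genes with a mean of at least 1 on that scale were tested (6782, leaving out 12 rows whose names a spreadsheet had damaged and 132 genes by the filter). That filter was set after the files were seen. A limma-trend model with 1 mean per assay and condition gave contrasts for footprints, mRNA and their interaction. It has 2 residual degrees of freedom, and the lone control of each assay is assumed to vary like the knockdown pairs. Tests were 2-sided with Benjamini-Hochberg adjustment at 0.05. Gene lists, 17 in all and 15 with at least 5 genes, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists were the Wnt pathway, Wnt targets, intestinal stem cell and differentiation genes, m6A writers, erasers and readers, ribosomal proteins, translation factors, the integrated stress response, p53 targets, the interferon response, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, proteasome, cholesterol synthesis, and fibroblast and blood cell markers. Values of some single members of these lists are not reported here.

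Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took YTHDF1, up to 10 rises and 10 falls per contrast with both knockdown libraries on 1 side of the control and a mean level at or above the lower quartile, places left over being filled by the smallest p, and a set of Wnt, stem cell and m6A genes. For RIP it took the 15 largest and 5 smallest ratios among genes with input at or above the median, and for m6A the 10 highest summed ratios. Chosen after the data were examined were the RIP listing test, the matched list presence tests, the comparison with transcript span, the shared input check, and settings without small RNA hosts or histone genes. The RIP values are deposited ratios without a pseudocount. Because the list is truncated, the planned test of RIP by m6A status ran within it.

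Medians of RIP ratios were compared by 100000 permutations within 10 groups by input level, and list presence by 10000. Coordinates are from the RefSeq table of the GRCh38 assembly, in which 94.9% of tested gene names were found. The fits were tested on simulated data of 6782 genes with 200 changed in footprints only. With variances drawn from the fitted prior, footprint changes of 2- and 4-fold were recovered in 0% and of 8-fold in 60.5% of genes. With each gene's own posterior variance, recovery was 52.5% at 4-fold and 96.0% at 8-fold, and 8.13% of the 8-fold calls were unchanged genes, above the nominal level. For translational efficiency the 8-fold recovery was 0% and 66.0%. The prior version was adopted after the other had been run, and both are given since recovery depends on this choice. The simulation gave each gene 1 spread in all libraries and independent noise. In the data the median spread between knockdown libraries was 0.354 for footprints and 0.225 for mRNA (SD, log2). The difference between knockdown libraries also correlated at 0.37 across genes between assays. Simulated recovery is therefore only a rough guide, and an absence of calls is weak evidence.

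Alternatives covered scaling, filters, pseudocounts of 0.1 and 5, left-out libraries, separate fits per assay, a block on replicate number, RIP thresholds and peak definitions. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Intervals cover counting error only.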

Results

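The series profiled HCT116, a human colorectal cancer cell line, after knockdown of YTHDF1, a cytoplasmic protein that binds N6-methyladenosine (m6A) in mRNA. The stated purpose was to find mRNAs whose translation YTHDF1 regulates. Ribosome profiling, which sequences the mRNA fragments protected by ribosomes, covered 2 knockdown libraries and 1 control library, and mRNA-seq covered the same numbers. An immunoprecipitation of YTHDF1-bound RNA (RIP) had 1 library and 1 input, and m6A-seq had 2 replicates. In all, 6782 genes of the expression table were tested. The footprint values of the table summed to 1229171 in the control, 940861 in knockdown 1 and 1042858 in knockdown 2, and its mRNA values to 341359, 345453 and 340208. These are sums of a relative unit over the listed genes, so the read depth behind each value is unknown. The labels do not say whether samples came from separate cultures. The limma p-values rest only on the spread between the 2 knockdown libraries of each assay. That spread may be technical, or may include a difference between hairpins if shY1-1 and shY1-2 are different ones.

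YTHDF1 itself (chromosome 20, 63195429 to 63216131) was lower in every knockdown library than in the control. Its mRNA value was 27.4 in the control and 8.22 ± 0.575 (SD, n = 2) in the knockdown, with single values of 8.62 and 7.81, or 0.300 of the control. Its footprint value was 61.4 in the control and 18.4 ± 2.11 (SD, n = 2) in the knockdown. The log2 changes were -1.62 ± 0.40 (SE) for mRNA and -1.69 ± 0.40 for footprints, on the log2(value + 1) scale. In limma over all genes neither passed the threshold, with adjusted p = 1.00 and 0.552 and unadjusted p = 0.00549 and 0.00456. The ratio of footprints to mRNA, the translational efficiency, stood at a log2 difference of -0.06 ± 0.56 for this gene, and at 0.43 with quantile normalisation and 0.22 with median centring.

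**Figure D1:**
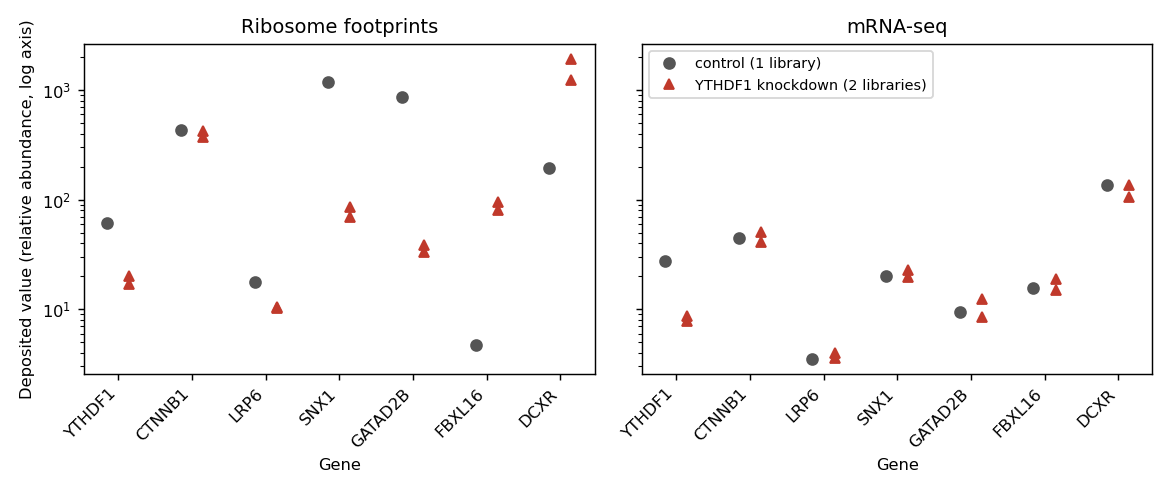
Deposited values of 7 genes in ribosome footprints (left) and mRNA-seq (right), on a log axis; circles are the 1 control library and triangles the 2 knockdown libraries. YTHDF1 is lower in both assays, with 27.4 against 8.62 and 7.81 in mRNA, while the SNX1 and GATAD2B differences appear in footprints and not in mRNA.

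The first comparison asked which mRNAs carried more or fewer ribosome footprints after knockdown. Footprints of 2 genes fell. SNX1, which encodes a sorting nexin of the endosome (chromosome 15, 64095982 to 64144231), went from 1173 in the control to 77.3 ± 10.8 (SD, n = 2). GATAD2B, which encodes a subunit of the NuRD chromatin-remodelling complex (chromosome 1, 153804725 to 153922972), went from 858 to 35.6 ± 3.62. Their log2 changes were -3.91 ± 0.33 (SE) and -4.56 ± 0.39, both with limma adjusted p = 0.0460. Their mRNA values were 20.2 in the control against 21.1 ± 2.11 for SNX1, and 9.39 against 10.4 ± 2.64 for GATAD2B. In the control library the footprint to mRNA ratio of SNX1 lay at the 99.7th percentile of all genes and that of GATAD2B at the 99.8th percentile, while in the knockdown libraries SNX1 lay at 81.7 and 74.7 and GATAD2B at 69.0 and 80.7. After median centring of the libraries the changes were -3.63 for SNX1 and -4.27 for GATAD2B and after quantile normalisation -3.62 and -4.15, while both calls were lost (adjusted p = 0.0643 and 0.0570), with a range of 0.000395 to 0.0654 over all settings, and each rests on the value of 1 control library. The count was 8 without footprint library 1 of the knockdown and 80 without footprint library 2, when the mRNA pair alone sets the spread.

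No other gene passed, and 600 genes had an unadjusted p under 0.05 in limma, 126 higher and 474 lower. With the replicate number as a block 30 genes passed (8 higher), FBXL16 and DCXR among them. The labels do not state that these numbers pair cultures. The count of genes with an unadjusted p under 0.05 depends on the fit, and was 1232 with that block. It was 912 without footprint library 1 of the knockdown and 1425 without footprint library 2, but 299 without mRNA library 1, 296 without mRNA library 2 and 296 with each assay fitted alone, against 339 expected by chance in the fit to all libraries. The remaining named genes are those with the smallest p and are given as values. On the higher side, FBXL16, an F-box protein, stood at 4.67 in the control and 87.8 ± 9.78 (SD, n = 2) in the knockdown (adjusted p = 0.0751). DCXR, a dicarbonyl and xylulose reductase, stood at 196 and 1583 ± 478 (adjusted p = 0.144). Log2 changes of THEM4, POLR1D, C15orf57, NUBPL, CDK17, SUZ12, ITGA3 and DVL2 were 2.16, 1.45, 1.62, 2.11, 2.11, 2.02, 1.69 and 1.84. On the lower side, PLCB1, a phospholipase C, stood at 330 in the control and 7.31 ± 5.29 in the knockdown (adjusted p = 0.141), and the gene holds the small RNA gene RNU105B. Log2 changes of SAMD4B, WARS, XYLT2, PCNX3, MRPL55, KDM6B and GLTSCR2 were -2.96, -2.32, -4.50, -3.09, -2.16, -2.93 and -2.02. Over all genes the median footprint change was -0.28, with -0.19 in knockdown 1 and -0.34 in knockdown 2, so that 69.4% of genes had a negative change. Median centring removes this shift.

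Among the Wnt and stem cell genes fixed beforehand, none passed in footprints. CTNNB1, which encodes beta-catenin, stood at 429 in the control and 397 ± 38.1 (SD, n = 2) in the knockdown, a log2 change of -0.11 ± 0.31 (SE), or 0.17 relative to the median of all genes, and the sign is positive under quantile normalisation and median centring. LRP6, a Wnt co-receptor, stood at 17.6 and 10.3 ± 0.0827, a change of -0.71 ± 0.46, or -0.43 relative to that median. TCF7L2, the transcription factor partner of beta-catenin, stood at 229 and 92.8 ± 71.6, with 42.2 in knockdown 1 and 143 in knockdown 2. Changes of CCND1 and CD44 were -0.52 and -0.03. Changes of SOX9 and METTL3 were 0.80 and -0.78, with 1.34 and -1.18 in knockdown 1 and 0.25 and -0.37 in knockdown 2. AXIN2, MYC, LGR5 and ASCL2 were not in the expression table, so their footprints and mRNA could not be tested. In the RIP input MYC stood at 43.0 FPKM and AXIN2 at 5.43. The genes tested were 15 of 36 listed Wnt targets, 33 of 67 Wnt pathway genes and 10 of 27 intestinal stem cell genes. They were 9 of 43 intestinal differentiation genes and 37 of 85 oxidative phosphorylation genes. The list results below therefore cover only part of each list.

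Of 15 gene lists tested on footprints, only the 22 p53 targets passed in limma camera at the preset correlation, on the higher side. Their median lay 0.61 above that of all genes (adjusted p = 0.0196). With an estimated correlation camera gave adjusted p = 0.940, and fry gave p = 0.806. The list stood 0.95 above all genes in knockdown 1 and 0.05 above in knockdown 2, 8 members were higher and 4 lower than the control in both libraries, and none passed singly. The largest mean differences came mostly from knockdown 1. BTG2 stood at 2.81 in knockdown 1 and -0.16 in knockdown 2, PHLDA3 at 2.05 and 0.40, and BBC3 at 1.74 and 0.07. No list passed without knockdown 1 of the footprint libraries. The Wnt pathway (33 genes) lay 0.12 above all genes and did not pass (adjusted p = 0.0614, and 0.0559 with median centring and 0.0541 with quantile normalisation). Oxidative phosphorylation (37 genes) lay 0.20 above all genes and did not pass (adjusted p = 0.0777), but passed with median centring (adjusted p = 0.00554) and quantile normalisation (adjusted p = 0.0359), and not with an estimated correlation (adjusted p = 0.940), with ATP5B at 0.68 and COX5A at footprint values of 148 in the control, 369 in knockdown 1 and 316 in knockdown 2. Translation factors (36 genes) lay 0.12 above (adjusted p = 0.901), with EEF2 at -1.56 and PABPC4 at 1.51. The integrated stress response list (22 genes) lay 0.07 above (adjusted p = 0.901). Its members went both ways, with 6 higher and 9 lower in both libraries. WARS and ATF4 stood at -2.32 and -2.10, and DDIT4 and ATF3 at 1.42 and 1.35. No member passed over all genes, while 2 members passed when adjusted over the list alone. Fibroblast and blood cell markers had 3 and 1 genes in the table and were not tested. Footprint values in the control, knockdown 1 and knockdown 2 were 10.5, 0.312 and 1.88 for FN1, 0.631, 13.2 and 3.71 for COL1A1, 2.49, 3.40 and 3.49 for VIM, and 15090, 10162 and 9485 for CD68. The mRNA values of CD68 in the same order were 19.9, 4.98 and 19.9, far below its footprint values, and the cause was not tested.

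For mRNA level the comparison asked which transcripts differed in abundance. No gene passed in limma, and 32 genes had an unadjusted p under 0.05 against 339 expected by chance. The latter count was 112 when footprint library 1 or footprint library 2 of the knockdown was left out, 17 without mRNA library 1 and 108 with each assay fitted alone. Without mRNA library 1 of the knockdown 1 gene passed. The fit shares 1 estimate of the spread with the noisier footprints. That sharing is not the whole reason for the low count, which stayed under 339 with each assay fitted alone. Across genes, mRNA knockdown 2 correlated at 0.982 with the control and at 0.959 with knockdown 1. For footprints these correlations were 0.950 and 0.925. In both assays the 2 knockdown libraries, which set the spread, were thus less alike than knockdown 2 and the control. With the replicate number as a block, 2 genes passed and 152 had an unadjusted p under 0.05 in limma. The smallest p on the higher side belonged to ARL14EP, at 9.50 in the control and 75.1 ± 3.20 (SD, n = 2) in the knockdown, and to ARMC8, at 13.6 and 98.1 ± 12.4. Their footprint values were 80.8 in the control against 76.3 ± 22.2, and 26.7 against 34.4 ± 12.6. WASHC4, ZNF740, PCCA, FAM98A, COPS4, KDM3A, DNAJC15 and ZC3H8 followed with log2 changes of 2.15, 1.31, 1.51, 1.26, 0.98, 1.44, 1.07 and 0.90. On the lower side YTHDF1 ranked beside RAD51B, a recombination protein, with changes of -1.62 and -1.85. OSBPL9, GABPB1, LPP, RAB28, PTMS, SYTL1, C14orf145 and IPP stood at -1.51, -1.28, -1.63, -1.41, -0.96, -1.91, -1.93 and -1.31. Mean changes of CTNNB1, TCF7L2, LRP6, CCND1, SOX9, CD44 and METTL3 lay between -0.20 and 0.37. Except for LRP6 and CCND1, the knockdown libraries of these genes lay on opposite sides of the control. TCF7L2 stood at 69.8 in the control, 47.8 in knockdown 1 and 89.7 in knockdown 2. In the same order SOX9 stood at 29.9, 60.4 and 24.8, and CD44 at 443, 294 and 505.

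At the preset correlation of 0.01, p53 targets were higher in mRNA as a group. Their median change was 0.56, and 16 of 22 members were higher than the control in both libraries and 0 lower in both. Limma camera gave adjusted p = 1.49e-07 at that setting. With the estimated correlation of 0.884 camera gave adjusted p = 0.867, and fry gave p = 0.551, so the group call rests on the preset. The members with the largest mean differences were BBC3 and BTG2, which act in apoptosis and growth arrest. BBC3 stood at 2.85 in knockdown 1 and 1.22 in knockdown 2, BTG2 at 3.05 and 0.86, SESN2 at 2.04 and 0.42, and TP53I3 at 1.83 and 0.41. Cell cycle genes were lower as a group at the preset, with a median change of -0.34 over 29 genes, 18 lower and 1 higher in both libraries. Camera gave adjusted p = 2.23e-05 at the preset and 0.867 with the estimated correlation of 0.604, and fry gave p = 0.510. The largest mean differences were those of MYBL2, at -1.93 in knockdown 1 and -0.15 in knockdown 2, AURKA at -1.15 and -0.18, and E2F1 at -1.32 and 0.01. Relative to all genes, the p53 list stood at 0.95 in knockdown 1 and 0.13 in knockdown 2, and the cell cycle list at -0.59 and -0.05. Without knockdown 1 of the mRNA libraries no list passed, and without knockdown 2 of the mRNA libraries 6 passed. No single member of either list passed.

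The other lists did not pass in mRNA. The smallest p among them belonged to cytosolic ribosomal proteins (47 genes, adjusted p = 0.0747), whose median relative to all genes was 0.28 in knockdown 1 and -0.07 in knockdown 2. Next were m6A writers, erasers and readers at -0.12 (16 genes, adjusted p = 0.141), a list that holds YTHDF1, oxidative phosphorylation at 0.07 (37 genes, 0.164) and Wnt targets at -0.21 (15 genes, 0.177). Medians relative to all genes were 0.18 for the interferon and double-stranded RNA response (17 genes, adjusted p = 0.277), 0.01 for glycolysis and hypoxia (21 genes, 0.277), -0.12 for cholesterol synthesis (14 genes, 0.321) and -0.04 for the proteasome (25 genes, 0.398). Examples are IRF7 at 0.67 and KDM3A at 1.44, ANGPTL4 at 1.76 in knockdown 1 and 0.49 in knockdown 2, and PSMD1 at -0.81 and -0.21.

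**Figure D2:**
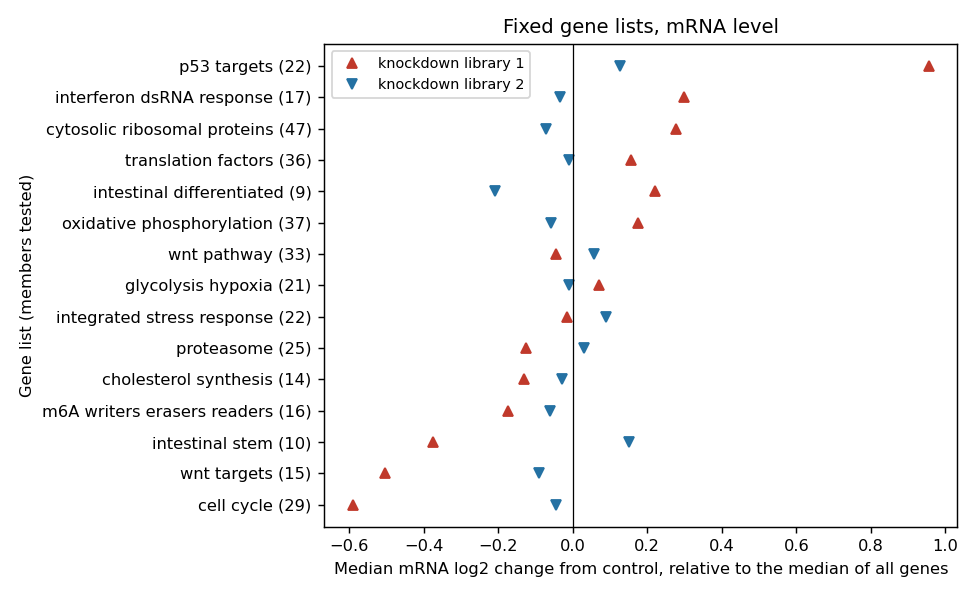
Median mRNA log2 change from the control library for each of 15 fixed gene lists, relative to the median of all genes, in knockdown library 1 (upward triangles) and knockdown library 2 (downward triangles). The p53 targets stand at 0.95 and 0.13 and the cell cycle list at -0.59 and -0.05, so the larger shift is in knockdown library 1.

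Translational efficiency addressed the purpose of the study directly, by testing the interaction of assay and condition in the same limma fit. No gene passed (smallest adjusted p = 0.349), and 185 genes had an unadjusted p under 0.05 against 339 expected by chance. The latter count was 518 without footprint library 1 of the knockdown and 724 without footprint library 2, and 62 and 60 without mRNA library 1 and 2. With the footprint to mRNA ratio taken per numbered pair, 454 genes had an unadjusted p under 0.05 in limma and 0 passed. The labels do not state that these numbers pair cultures. In simulated data of this design, 8-fold efficiency changes were recovered in 0% to 66.0% of genes and 2-fold changes in 0%, depending on the simulated spread. In those simulations, whose noise differs from that of the data, 2-fold changes were thus not detected per gene. Without mRNA library 1 of the knockdown 1 gene passed. The smallest p belonged to GATAD2B and SNX1, at -4.67 ± 0.55 (SE) and -3.97 ± 0.47. PLCB1, ARL14EP, SAMD4B, ZNF778, WARS, GLTSCR2 and ARMC8 stood at -5.88, -2.97, -2.32, -2.82, -2.19, -2.03 and -2.45, and CCDC51 had footprint values of 482 in the control and 149 ± 26.9 (SD, n = 2) in the knockdown. On the higher side FBXL16, DCXR, THEM4, POLR1D, NFIX, RAD51B, DVL2, SUZ12 and C15orf57 stood at 3.89, 3.15, 2.13, 1.52, 2.93, 2.15, 2.06, 2.05 and 1.55, and EMP3 had footprint values of 359 and 698 ± 29.5. CTNNB1, LRP6 and TCF7L2 stood at -0.13 ± 0.44, -0.78 ± 0.65 and -1.46 ± 1.03, and CCND1, SOX9, CD44 and METTL3 at -0.42, 0.43, 0.18 and -0.80. The median over all genes was -0.27.

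No gene list passed for translational efficiency in limma camera, and 2 had an unadjusted p under 0.05. Without mRNA library 2 of the knockdown 3 lists passed. The 33 Wnt pathway genes tested had the smallest p, with a median 0.07 above all genes (limma camera adjusted p = 0.144), where the median change was -0.20 and the mean 0.03. Of its members CHD8 stood at -3.17, from footprint values of 1275 in the control, 19.6 in knockdown 1 and 1228 in knockdown 2, and DVL2 at 2.06. Wnt targets (15 genes) lay at -0.05 relative to all genes (adjusted p = 0.938). Intestinal stem cell genes (10) lay at 0.38 (limma camera adjusted p = 0.525), with KCNQ1 at 2.02 and ZBTB38 at -1.25. Intestinal differentiation genes (9) lay at 0.01 (limma camera adjusted p = 0.792) with a negative mean, led by KRT20 at -1.95. KCNQ1 and KRT20 had low values. In the control, knockdown 1 and knockdown 2, KCNQ1 had footprints of 0.950, 1.13 and 9.13 and mRNA of 2.47, 0.344 and 2.09. Footprints of KRT20 in that order were 6.34, 1.10 and 0.473. Writers, erasers and readers of m6A (16) lay at 0.29 (adjusted p = 0.468), with 7 members higher and 7 lower in both libraries, METTL5 and METTL16 at 1.07 each, and RBM15B and METTL3 at -0.97 and -0.80. Cytosolic ribosomal proteins (47) lay at -0.10 (adjusted p = 0.176), with -0.37 in knockdown 1 and 0.22 in knockdown 2.

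The RIP comparison asked which RNAs were recovered with YTHDF1. The list analysed here held 3929 genes, all with an input of at least 1 FPKM and a ratio of at least 1.5, so it gives enriched genes and no background. The median ratio was 2.28, and 2514 genes (64.0%) reached 2-fold, 430 reached 4-fold and 24 reached 10-fold. Histone genes led. Of the 24 genes at 10-fold or more 12 were genes named HIST, the highest at 650-fold. Among genes with input at or above the median, 8 of the 15 largest ratios were HIST genes, with HIST1H2AM at 417-fold, HIST1H2AJ at 170 and HIST2H2AA4 at 79.8. The 14 such genes had a median of 73.6-fold, and only 6 carried an m6A peak in both replicates. These genes have near-identical copies and transcripts mostly without a poly(A) tail, and how the library preparation treated them is not given in the sources used here. The other 7 of these 15 were FAT1, a cadherin, at 12.8-fold, DYNC1H1, the dynein heavy chain, at 11.9, PLEC at 10.2, TNRC18 at 8.56, UBR4 at 8.51, EP400 at 8.38 and HUWE1 at 8.32. The smallest ratios, SFSWAP, LRPAP1, JMJD8, C3orf18 and PRAME, lay at 1.5. With 1 RIP and 1 input library there was no replicate check.

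Of Wnt genes, LRP6 was enriched 4.74-fold (5.21 against 1.10 FPKM), AXIN2 3.07-fold, CTNNB1 2.33-fold, MYC 1.92-fold, TCF7L2 1.86-fold and CCND1 1.53-fold. YTHDF1 stood at 2.5 and METTL3 at 1.89, and among m6A genes RBM15 stood at 10.7 and YTHDF3 at 4.95. Of the 33 Wnt pathway genes in the expression table, 19 (57.6%) were in the RIP list against 35.7% in matched random lists (adjusted p = 0.0773, permutation). For Wnt targets the count was 10 of 15 against 31.3% (adjusted p = 0.0435, permutation), and for cytosolic ribosomal proteins 1 of 47 against 17.2% (adjusted p = 0.0435, permutation). These tests run across genes of 1 pair of libraries and were chosen after the data were examined. The random lists were not matched for transcript length. Among m6A-marked genes of the expression table, the percent listed rose from 15.4% at the shortest transcript spans to 74.7% at the longest. Length was therefore not separated from list membership. Counting genes outside that table too, the median ratio of 17 listed Wnt targets lay at the 39.6th percentile of matched lists. That of 25 listed Wnt pathway genes lay at the 97.4th.

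Enrichment was higher for longer transcripts. Taking the end of the last m6A window as a lower bound of transcript length, the RIP ratio of 3380 m6A-marked genes had a Spearman correlation of 0.421 with span across genes, which are not independent replicates. The median ratio was 1.95 in the group with the shortest spans (median 1500 bases) and 3.15 in the group with the longest (median 5500 bases).

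**Figure D3:**
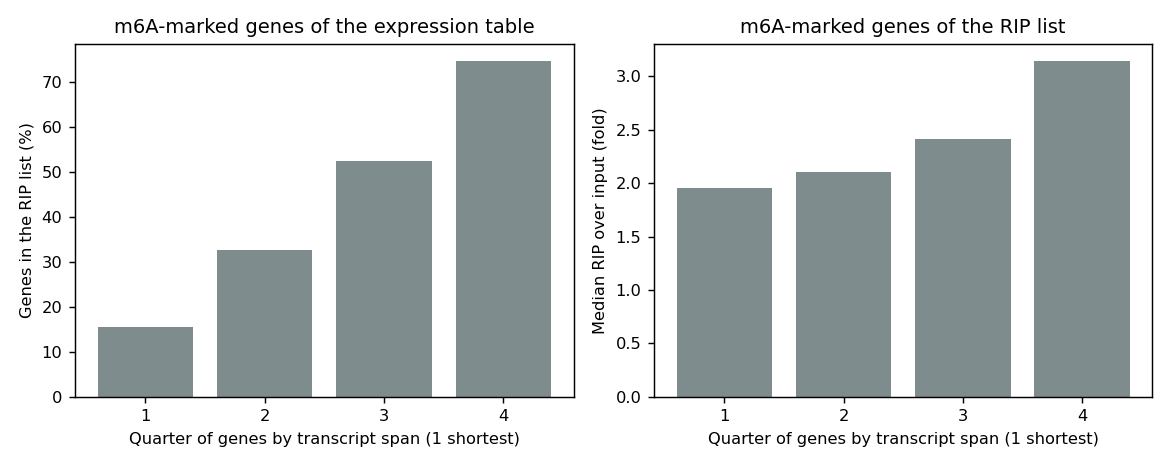
m6A-marked genes in 4 equal groups by transcript span (shortest 1, longest 4). Left, the percent of genes of the expression table that are in the RIP list, from 15.4% to 74.7%, with groups made over that table; right, the median RIP over input of genes in the RIP list, from 1.95 to 3.15 fold, with groups made over the RIP list.

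The m6A-seq replicates were compared by peak overlap. Replicate 1 listed 24452 peaks in 8680 genes and replicate 2 listed 24815 peaks in 8932 genes, after entries with damaged names were left out. Of replicate 1 peaks, 74.4% (95% Wilson interval 73.90% to 74.99%) overlapped a replicate 2 peak by at least 1 base, against a mean of 29.2% after 20 random shifts within genes. Peaks were found in both replicates for 8063 genes, a Jaccard index of 84.4%. Across 17961 shared peaks the authors' ratio of peak over input had a Spearman correlation of 0.787. The lists share an input: in all 5960 windows with identical borders in both lists, the input signal was equal within a relative tolerance of 1e-06, while the immunoprecipitate signal was equal in 3. The overlap and the correlation therefore do not come from independent inputs.

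Assigned positions lay in 12 pentamers of the RRACH consensus only. Positions thus appear to have been restricted to that consensus, so its presence is no independent evidence of m6A. GGAC followed by A, C or T made up 30.7% of peaks in replicate 1 and 29.5% in replicate 2, against 25% if the 12 were equally frequent. That share is not a background taken from transcript sequence, so it does not measure enrichment. The share did not differ detectably between stronger and weaker peaks (Fisher's exact test, p = 0.390 and 0.956). CTNNB1 had 4 peaks in each replicate and its highest ratios were 8.41 and 7.23. LRP6 had 8 and 7 peaks, TCF7L2 7 and 3, AXIN2 6 and 3, SOX9 5 and 5, CCND1 5 and 3, YTHDF1 3 and 3, MYC 1 and 1, CD44 1 and 1, and METTL3 1 and 0. The 10 genes with the highest summed ratio were BAZ1B, TSPAN33, SPECC1, CUL4B, TOMM70A, MTRNR2L1, RNF213, IMPAD1, AP5B1 and SMC2. Near-zero input set most of these sums, as for BAZ1B with an input signal of 0.0132.

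Genes with m6A peaks were more enriched in the RIP than genes without. Within the RIP list, the median ratio was 2.32 for 3380 genes with a peak in both replicates and 2.03 for 271 genes with a peak in neither, a log2 difference of 0.19 (permutation within deciles of input, p = 1e-05, the smallest that 100000 resamples give). Among genes of the expression table, 43.8% (2155 of 4918) of m6A-marked genes were in the RIP list against 9.60% (109 of 1135) of unmarked genes, a difference of 34.2 points where matched permutations gave 3.86 (p = 0.0001, the smallest that 10000 resamples give). Both are tests across genes of 1 pair of libraries. Genes without a peak have no span here, so transcript length was not matched.

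The last comparison asked whether RIP-enriched, m6A-marked genes changed in translational efficiency after knockdown, as the study's question implies. No difference was detected. The median change was -0.29 for 1396 genes with both marks against -0.26 for the others, a difference of -0.03 (limma camera adjusted p = 0.961; p = 0.972 with an estimated correlation). For 4918 genes with m6A in both replicates the difference was -0.01, and for 1535 genes at least 2-fold in the RIP it was -0.02, both with adjusted p = 0.961. For m6A the mean difference was 0.02, and for the RIP genes camera's direction was up, so median, mean and test differ in sign. The libraries differed in direction: genes with both marks stood 0.04 above the other genes in knockdown 1 and at -0.14 in knockdown 2. In footprints and mRNA taken alone, the same 1396 genes differed from the others by -0.05 and -0.01 (adjusted p = 0.971 and 0.946). With a 4-fold RIP threshold the mRNA difference of genes with both marks was 0.09 over 241 genes, with 0.09 in knockdown 1 and 0.08 in knockdown 2 (limma camera p = 0.0499, not adjusted, and p = 0.421 with an estimated correlation).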

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

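Removal of small RNA hosts or histone genes, left-out libraries for list counts and a RIP pseudocount of 1 were chosen after seeing the data. The others were planned, and the estimated correlation was part of the planned list tests. The 2 footprint calls went to 0 with quantile normalisation, median centring, no filter and pseudocount 0.1. In these settings the adjusted p of SNX1 and GATAD2B ran from 0.0515 to 0.0654, and over all settings from 0.000395 to 0.0654. Leaving out a knockdown library gave 2 to 80 footprint calls, 0 to 1 for mRNA and 0 to 1 for efficiency. The 80 came without footprint knockdown 2 and 8 without footprint knockdown 1, where the mRNA pair alone sets the spread. With the replicate number as a block, 30 footprint genes (8 higher) and 2 mRNA genes passed, and 0 for efficiency as a ratio per pair. The numbers are not stated to pair cultures; the difference between knockdown libraries correlated at 0.37 (Spearman 0.391) across genes between assays.

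Footprint lists passing went from 1 to 2 with quantile normalisation or median centring, when oxidative phosphorylation passed too, and 0 with an estimated correlation, and mRNA lists from 2 to 0 with an estimated correlation. Leaving out libraries gave 0 to 1 footprint lists, 0 to 6 mRNA lists and 0 to 3 efficiency lists. The 3 came without mRNA knockdown 2.

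Of 1051 other values with a test for named genes and lists, 996 kept direction and call, 24 gained a call, 11 lost one and 20 changed sign. The 996 do not measure stability. Some settings leave a gene's change as it is by construction, as for FBXL16 footprints at 3.964 with no filter and with each assay fitted alone. Most named genes had no call to lose and were chosen with both knockdown libraries on 1 side. No gene that changed sign passed in any setting, and the cause was not tested. With quantile normalisation and median centring, footprint changes became 0.084 and 0.18 for CTNNB1 and 0.16 and 0.27 for CD44, and efficiency changes 0.43 and 0.22 for YTHDF1 and 0.057 and 0.15 for CTNNB1. With knockdown libraries left out, values ran as follows. Footprints of CD44 ran from -0.147 to 0.10. In mRNA CTNNB1 ran from -0.13 to 0.162, TCF7L2 ran from -0.537 to 0.36, SOX9 from -0.26 to 0.992, CD44 from -0.591 to 0.19 and METTL3 from -0.34 to 0.385. Efficiency ran from -0.237 to 0.112 for YTHDF1, -0.373 to 0.112 for CTNNB1, -0.19 to 1.057 for SOX9 and -0.334 to 0.689 for CD44. The 172 values without knockdown 1 or 2 in both assays have no test and say nothing of stability; 9 of them differ in sign from the reported value.

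The efficiency difference of m6A-marked genes was 0.02 with a peak in either list (0.015). By knockdown library it ran from -0.08 to 0.04 for m6A, -0.13 to 0.05 for RIP and -0.14 to 0.04 for both. RIP counts were 3929 at 1.5-fold, 430 at 4-fold, 518 with input in the upper quartile and 941 with pseudocount 5. The filter on input equals the list's own. Shared peaks were 66.3% at 50% reciprocal overlap and 67.6% in the stronger part of each list. The RIP difference by m6A status ran from 0.18 to 0.24.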

Other observations

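Among the p53 target and cell cycle tests, the footprint shift tests and the list tests below, all were chosen after the result was seen except the correlations with transcript span and peak number, which were set out before they were computed.

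Gene groups differed in m6A status. Of the 29 cell cycle genes in the expression table, 28 (96.6%) had a peak in both replicates against 75.3% in matched random lists (permutation adjusted p = 0.025). Oxidative phosphorylation genes had 15 of 37 (40.5%) against 71.8% (adjusted p = 0.003), and cytosolic ribosomal proteins 22 of 47 (46.8%) against 69.8% (adjusted p = 0.018). Transcript length was not matched. ATF4, the transcription factor of the integrated stress response, whose mRNA is translated through upstream reading frames, had footprint values of 720 in the control, 213 in knockdown 1 and 131 in knockdown 2 and mRNA values of 181, 168 and 196 (unadjusted p = 0.00106, adjusted p = 0.445 for footprints in limma). EEF2, the elongation factor that moves the ribosome, had footprint values of 27004, 7749 and 10767 (adjusted p = 0.552). Both were chosen after their values were seen.

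Footprint values were lower in both knockdown libraries for most genes. The deposited filter on control values predicts a shift near 0 in genes far above it, and decile 10 of 10 by mean level still shifted by -0.228 ± 0.019 (bootstrap SE), which argues against the filter as the whole cause. The 10 highest genes of the table taking more of the values would need the share left for other genes to drop as much as the median, and the lower of its 2 log2 changes was -0.026 against medians of -0.19 and -0.34. Lower translation of most mRNAs stays open, since the median efficiency change of -0.271 is in relative units with no spike-in, and scaling of the libraries by the authors stays open as well.

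The p53 target list was higher and the cell cycle list lower, mostly in knockdown library 1. A scaling factor for that library would move both lists the same way, and the cell cycle list moved by -0.589 while the p53 list moved by 0.95. A stronger knockdown in library 1 stays open, since YTHDF1 mRNA was higher there than in library 2 by 0.127 (log2), less than the median spread of 0.225. A change shared by both libraries also stays open: in knockdown 2 mRNA the p53 list lay at the 97.7th percentile of matched lists and the cell cycle list at the 15.8th (15.78). Culture state or hairpin, on 1 control library, cannot be separated from it.

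The RIP ratio was higher for longer transcripts. Across 3380 m6A-marked genes, the correlation with span given peak number and input was 0.274 ± 0.017 (bootstrap SE). The correlation with peak number was 0.305 ± 0.016 alone and 0.025 ± 0.018 given span and input. Span and peak number come from the same peak lists, so holding span fixed can also remove a relation with m6A. This comparison therefore cannot decide, and more m6A sites stay open as a cause. A candidate explanation is transcript length itself or coverage along the transcript, and span is known here only from the last peak, so a gene with a late peak counts as long. The same relation could contribute to the higher RIP listing of m6A-marked genes.

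Genes that hold a small RNA gene made up 3.88% of the genes with a known location and 6.32% (6 of 95) of the 100 largest footprint changes (Fisher's exact test, p = 0.186).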
